A study of Homo sapiens with 18 samples.

How the data were processed

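The series holds 18 libraries from cells labelled A549: 3 groups (untreated, 10 mg/L BPQD, 100 mg/L TiO2, the exposures lasting 24 h), each with 3 input RNA-seq and 3 m6A immunoprecipitation libraries. Per the labels, cells were grown in DMEM/F-12, total RNA was extracted with Trizol and had a RIN above 7. Libraries were assigned to groups from their titles.

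The expression table holds, per the file headers, FPKM for 36576 genes in the 9 input libraries, made by the authors with the scaling they deposited. The authors' notes name HISAT2, with its version not given in the sources used here, and StringTie 1.3.0, without their roles, and list the mouse build mm10. The gene IDs are human, however, and of 24557 symbols found in a GRCh38 annotation all lay on the same chromosome and 92.8% started near the same place, so coordinates are read as GRCh38. Of 36576 gene IDs, 36346 were found in a table of names. Read counts and depth are not given, so no count model was fitted, and precision rests on the 3 libraries per group. The table has no columns for the immunoprecipitated libraries, so no enrichment per gene and library was computed here.

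The authors deposited a table of differential m6A peaks for each material against control. It gives, per the file headers, a log2 fold change of m6A enrichment, a p-value and the log10 of an FDR, which is treated as a score, made by the authors with a peak caller and a pooling of replicates that are not given in the sources used here. The authors also deposited in these tables a log2 ratio of mean input FPKM, which was recomputed from the expression table and matched, and a p-value and q-value of expression that were not used here. The 12 other columns of FPKM per sample in the peak tables repeat input libraries and were not used. The peak tables have no strand column, so overlap ignores strand, although the same strand had been planned. Peaks are given as a start and an end, with a median width of 658 bases under BPQD and 789 under TiO2 and a highest of 1316931, so they can include introns. Repeated entries numbered 1 and 5.

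Expression was tested in R 4.3.3 with limma 3.58.1 on log2(FPKM + 1) for the 12224 genes with a mean of at least 1 FPKM over all 9 libraries. Group means were fitted to all 9 libraries, which share 1 estimate of the spread, with a trend in the moderated variance. BPQD against control, TiO2 against control and BPQD against TiO2 were tested two-sided with Benjamini-Hochberg adjusted p under 0.05. The replicate numbers were not used as pairs. A set of 33 gene lists was fixed in advance, of which 30 had at least 3 measured members and were tested with camera (limma) at an inter-gene correlation of 0.01, adjusted over 90 tests, and again with an estimated correlation. Camera compares a list with all other tested genes. Members were also adjusted over the list alone. The lists covered m6A writers, erasers and readers, NRF2, ATF4, p53 and NF-kB targets, metallothioneins, the unfolded protein response, chaperones, interferon-stimulated genes, cell cycle, histones, DNA repair, glycolysis, hypoxia, sterol and fatty acid synthesis, lysosome, iron, epithelial-mesenchymal transition, the BCL2 family, oxidative phosphorylation, mitochondrially encoded mRNAs, ribosomal proteins, immediate early genes, phosphate handling, endocytosis, and markers of epithelium, fibroblasts, leukocytes and endothelium.

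Genes were named by a rule fixed in advance. For each comparison these were the 8 largest rises and 8 largest falls among called genes with a symbol and groups that do not overlap, up to 4 called members of each list with the largest change, and all m6A writers, erasers and YTH readers. For each peak table these were the 6 higher and 6 lower peaks with the smallest p in genes with a mean of at least 1 FPKM, and differential peaks in m6A genes or in genes named for expression. Some genes that meet this rule are not reported here. The genes with known levels in A549 were added after their values had been seen.

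The response shared by the materials was set against 100 simulations of unchanged groups that use the same controls. Peaks were counted at the authors' p under 0.05, and position was compared by Fisher's exact test over peaks, with pooling over 10 bins of mean FPKM by the Mantel-Haenszel method. Overlap needed at least 1 base. For the relation to expression, 1 peak per gene was kept, that with the smallest p, and set against the log2 ratio of mean FPKM in the same deposited table, and, as also planned, against the limma fold changes. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

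The steps were tested on simulated data. In 12224 simulated genes, limma recovered 89% to 93% of 100 genes changed by 1 on the log2 scale and 66% to 73% of 100 changed by 0.5, and called 6 or 7 others. A simulated list shifted by 0.3 was called at adjusted p = 8.73e-26, and at adjusted p = 0.00159 with an estimated correlation, while none of 87 other tests was called. A simulated trend with gene span was removed by the correction used, and the pooled odds ratio had a median of 1.00 and 1.99 for true values of 1 and 2.

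Alternatives fixed in advance covered the pseudocount, the filter, the scaling (TPM, median centring, quantile), a replicate block, the variance trend, array weights, the libraries fitted, each replicate left out, the correlation used by camera, and the thresholds and overlap of peaks. Added after seeing the data were a rescaling without genes like ribosomal RNA, corrections for gene span and expression level, pathways of the KEGG annotation in the deposited table, and peak positions pooled over expression or restricted to genes not called. The number of higher peaks that the expression bins give for a list was added then as well. Sequence motifs were not analysed here, since no genome was used.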

Results

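RNA was sequenced from cells labelled A549, a human lung adenocarcinoma line, left untreated or exposed for 24 h to 10 mg/L black phosphorus quantum dots (BPQDs) or to 100 mg/L titanium dioxide (TiO2). Each of the 3 groups had 3 input RNA-seq libraries and 3 libraries of RNA enriched with an antibody against N6-methyladenosine (m6A), an internal methyl mark of mRNA. The series asks whether the RNA methylation of these cells changed with nanomaterial exposure. The doses of the materials differed, so the comparison between them is one of the exposures as given. Expression was read from the 9 input libraries as FPKM values made by the authors, and m6A from the authors' deposited tables of differential peaks. Read counts were not given, so the depth of each library is unknown and no interval from counting can be attached to a value. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Throughout, mean FPKM is given ± SD and log2 fold change ± SE, with n = 3 libraries per group and Benjamini-Hochberg adjusted p from limma.

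A few genes with known levels in A549, chosen after their values had been seen, were examined beside the comparisons. CDKN2A (chromosome 9, 21967753 to 21995301), the p16 gene that is homozygously deleted in A549, had 24.2 ± 2.77 FPKM in control cells, 19.5 ± 0.380 under BPQD and 20.9 ± 0.591 under TiO2. Its neighbour CDKN2B had 10.7 ± 0.188, 7.44 ± 0.273 and 9.94 ± 0.276 FPKM. The aldo-keto reductases AKR1B10 and AKR1C1 and the aldehyde dehydrogenase ALDH1A1, which are abundant in A549, reached at most 0.998, 1.14 and 0.116 FPKM in any of the 9 libraries. The alveolar type II gene SFTPB and the lung lineage factor NKX2-1 reached at most 0.0336 and 0.0970 FPKM. The cells are called by their label below, and their identity was not examined by genotype.

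The libraries of each group lay together. Across the 12224 genes with a mean of at least 1 FPKM, the correlation of log2 values between libraries was 0.980 to 0.983 within groups and 0.966 to 0.975 between groups. The first component of a principal component analysis held 28.4% of the variance and the second 21.6%. The sum of FPKM over all genes was 222081 ± 652 in control libraries, 213571 ± 592 under BPQD and 219559 ± 110 under TiO2. Genes like ribosomal RNA, picked by clone name, held 1.49% ± 0.00811 of the control sum, 0.665% ± 0.00434 under BPQD and 0.715% ± 0.00585 under TiO2. Other ribosomal RNA genes were not counted in this share.

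**Figure D1:**
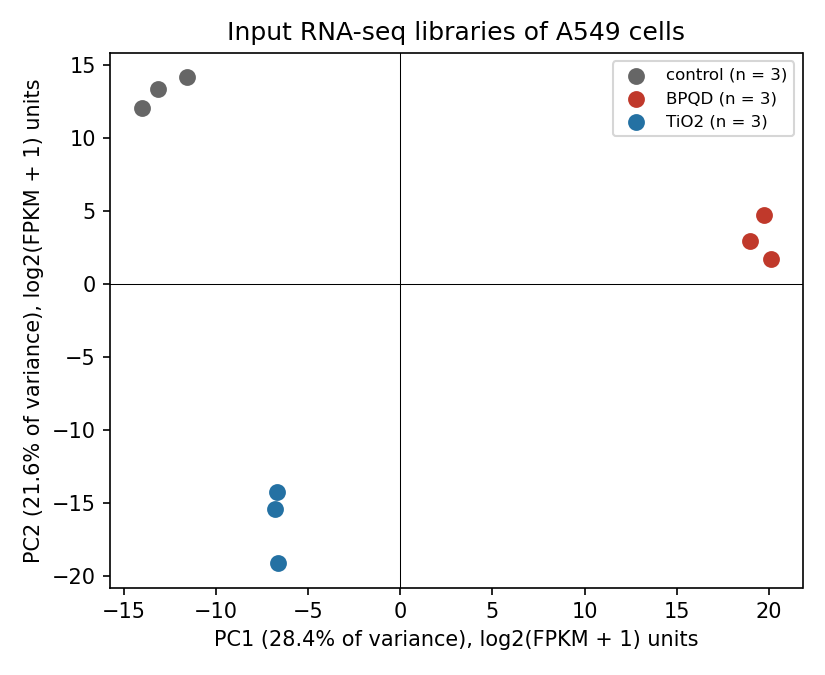
Principal component scores of the 9 input libraries from log2(FPKM + 1), with the share of variance on each axis (28.4% and 21.6%); each point is 1 library, coloured by group. The 3 libraries of each group lie together and apart from the other groups.

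BPQDs were compared with untreated cells to ask which transcripts differed after exposure to black phosphorus. The G2/M, DNA repair, m6A writer and m6A reader lists were called higher under BPQD by camera, with 11 of 22, 10 of 18, 7 of 12 and 8 of 15 genes higher. The lists of glycolysis, nuclear oxidative phosphorylation, metallothioneins and epithelial genes were called lower. None of these list calls held with an estimated correlation (adjusted p = 0.0867 to 0.140). The largest falls were in 3 short noncoding RNAs made by RNA polymerase III. RN7SK (chromosome 6, 52995621 to 52995948), which holds the elongation factor P-TEFb inactive, had 3.75 ± 0.360 FPKM against 37.4 ± 4.60 in control cells (log2 fold change -3.01 ± 0.27, adjusted p = 0.000112). RPPH1 (chromosome 14, 20343075 to 20343407), the RNA of ribonuclease P, fell by 2.87 ± 0.12 on the log2 scale, and RMRP (chromosome 9, 35657754 to 35658017), the RNA of ribonuclease MRP, fell by 2.54 ± 0.17.

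Of 12224 genes tested with limma, 5384 (44.0%) changed, 2524 higher and 2860 lower. The median absolute log2 fold change of these genes was 0.27, and 63 changed by at least 1 on the log2 scale, 36 of them upward. The 3 BPQD and 3 control libraries did not overlap in 6792 genes (55.6%), where chance gives 10%. With values rescaled to TPM the share of higher genes among the changed ones moved from 46.9% to 58.3%, so no balance between rises and falls is read from these counts.

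Among the largest rises, LINC02595 (chromosome X, 45848074 to 45851490) had 5.02 ± 0.134 FPKM against 0.847 ± 0.145 (log2 fold change 1.71 ± 0.09, adjusted p = 1.32e-05). CASC19, a noncoding RNA near MYC (chromosome 8, 127072694 to 127227541), rose by 1.51 ± 0.25, and NEAT1 (chromosome 11, 65422774 to 65445540), the scaffold of paraspeckles, rose by 1.51 ± 0.31 (adjusted p = 0.00559). UPK3BL1 (2.47 ± 0.59), SCARNA12 (1.42 ± 0.46), NKRF (1.36 ± 0.43) and the read-through transcript SENP3-EIF4A1 (1.58 ± 0.43) rose with wide errors. RPL36A-HNRNPH2, also a read-through transcript, was listed at 0 in all control libraries and had a mean of 26.8 FPKM under BPQD, so no fold is given. Besides the polymerase III transcripts, the largest falls were ABHD14B (-2.15 ± 0.53), TAX1BP3 (-1.53 ± 0.43), PXDC1 (-1.50 ± 0.34), LASP1 (-1.45 ± 0.38) and RAB40C (-1.40 ± 0.30). Read-through and overlapping genes share sequence with their neighbours, and the calls of RPL36A-HNRNPH2, TAX1BP3, SCARNA12 and NKRF were lost in several of the other settings tried. The call of LASP1 was lost without control replicate 1 or 2, and that of SENP3-EIF4A1 without BPQD replicate 2 or control replicate 3.

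The m6A machinery was examined member by member. Of 12 genes that write the mark or belong to related methyltransferases, 7 rose, 1 fell and 4 did not pass the test, and 8 rose and 1 fell when adjusted over the list alone. The catalytic METTL3 (chromosome 14, 21498133 to 21511342) had 7.84 ± 0.268 FPKM against 6.63 ± 0.146 (log2 fold change 0.21 ± 0.06, adjusted p = 0.0168), a call lost without BPQD replicate 2 or control replicate 1. Its partner METTL14 (chromosome 4, 118685392 to 118715433) had 2.77 ± 0.394 against 1.56 ± 0.0275 (0.55 ± 0.11, adjusted p = 0.00472). METTL16 (0.30 ± 0.08), WTAP (0.15 ± 0.04), VIRMA (0.26 ± 0.05), ZC3H13 (0.20 ± 0.03) and ZCCHC4 (0.42 ± 0.06) also rose, and the cap methyltransferase PCIF1 fell (-0.50 ± 0.04). The call of WTAP was lost without BPQD replicate 1 or control replicate 3, and that of METTL16 without BPQD replicate 3. CBLL1 (0.83 ± 0.35, adjusted p = 0.0875), RBM15 (0.44 ± 0.19), RBM15B (0.03 ± 0.03) and METTL5 (0.17 ± 0.07) did not pass the test. CBLL1 and RBM15 passed with only the 6 libraries compared, RBM15B with TPM, and METTL5 with TPM and without genes like ribosomal RNA. The list median was 0.23 with a camera adjusted p of 0.0143, and adjusted p = 0.0952 with an estimated correlation. Of the erasers, ALKBH5 (chromosome 17, 18183078 to 18209954) fell from 33.5 ± 1.19 to 28.8 ± 0.323 FPKM (-0.21 ± 0.03, adjusted p = 0.000846), and FTO had a log2 fold change of 0.05 ± 0.27 (adjusted p = 0.903); 2 genes are too few for a list test.

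Among 15 readers of the mark, 8 rose, 1 fell and 6 did not pass the test, with the same counts adjusted over the list alone. The nuclear reader YTHDC1 rose from 9.78 ± 1.02 to 15.3 ± 1.3 FPKM (0.60 ± 0.08, adjusted p = 0.000618), as did YTHDC2 (0.24 ± 0.03), HNRNPA2B1 (0.43 ± 0.04) and EIF3A (0.42 ± 0.02), and IGF2BP2 fell (-0.45 ± 0.05). The cytoplasmic readers YTHDF1 (0.05 ± 0.03), YTHDF2 (0.90 ± 0.47) and YTHDF3 (-0.58 ± 0.46) did not pass. YTHDF2 BPQD vs control moved to 0.37 without BPQD replicate 3, and to 1.35 without BPQD replicate 1, where it passed. YTHDF1 passed with TPM and without genes like ribosomal RNA. The median of the list was 0.21 (camera adjusted p = 0.00685; adjusted p = 0.140 with an estimated correlation).

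The lists of G2/M and DNA repair genes were called higher by camera, and that of G1/S and replication was not called. Of 22 G2/M genes, 11 rose and none fell (12 and 0 adjusted over the list alone), among them BUB1B (0.34 ± 0.06), CENPE (0.33 ± 0.03), TPX2 (0.32 ± 0.02) and KIF11 (0.27 ± 0.03), with a list median of 0.17 (camera adjusted p = 0.000906; adjusted p = 0.0867 with an estimated correlation). Of 18 DNA repair genes, 10 rose and none fell over all genes and also adjusted over the list alone. Examples were BRCA1 (0.56 ± 0.14) and XRCC2 (0.47 ± 0.07), and the list median was 0.17 (camera adjusted p = 0.00378; adjusted p = 0.104 with an estimated correlation). The 22 genes of G1/S and replication split, 6 higher and 5 lower (7 and 5 adjusted over the list alone), with CCNE1 down (-0.75 ± 0.12) and no list call (median 0.03, camera adjusted p = 0.304). Of 11 replication-dependent histone genes, 3 rose and 3 fell (median 0.03, camera adjusted p = 0.713).

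The lists of glycolysis and nuclear oxidative phosphorylation were called lower by camera. Of 18 glycolysis genes, 1 rose and 10 fell, among them SLC2A1, the glucose transporter GLUT1 (-0.41 ± 0.03), ALDOC (-0.46 ± 0.09) and the lactate exporter SLC16A3 (-0.37 ± 0.07); the list median was -0.31 (camera adjusted p = 0.00364; adjusted p = 0.0912 with an estimated correlation). Of 23 nuclear genes of oxidative phosphorylation, none rose and 13 fell, including COX5B (-0.41 ± 0.03), NDUFA4 (-0.31 ± 0.03) and UQCRC1 (-0.30 ± 0.03), with a median of -0.17 (camera adjusted p = 0.00378; adjusted p = 0.0867 with an estimated correlation). The 13 mRNAs encoded by mitochondrial DNA went the other way: 7 rose and none fell, led by MT-ND4L (0.50 ± 0.05), MT-CYB (0.36 ± 0.06) and MT-ND4 (0.35 ± 0.04). Their median was 0.25 (camera adjusted p = 0.0143), their genes moved together, and adjusted p = 0.337 with an estimated correlation. Mitochondrial mRNA held 0.234% ± 0.00525 of the FPKM sum under BPQD and 0.177% ± 0.0244 in control cells. Of 17 hypoxia targets 3 rose and 9 fell, among them ANGPTL4 (-0.84 ± 0.09), NDRG1 (-0.58 ± 0.11) and CA9 (-0.46 ± 0.06). Their median was -0.30 (camera adjusted p = 0.0481; adjusted p = 0.120 with an estimated correlation), and this call was lost without BPQD replicate 1, control replicate 1, or TiO2 replicate 2 or 3.

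The metal-binding metallothioneins MT1X (-0.50 ± 0.03), MT2A (-0.43 ± 0.02) and MT1E (-0.18 ± 0.02) all fell, MT2A from 176 ± 1.29 to 131 ± 1.28 FPKM (list median -0.43, camera adjusted p = 0.00442; adjusted p = 0.0912 with an estimated correlation). The 4 epithelial genes that were measured, of 17 listed, also fell: KRT18 (-0.51 ± 0.02), KRT7 (-0.48 ± 0.03), MUC1 (-0.46 ± 0.04) and ABCA3 (-0.24 ± 0.03), with a median of -0.47 (camera adjusted p = 0.00227; adjusted p = 0.0986 with an estimated correlation). Of 4 fibroblast genes measured, PDGFRB (-0.61 ± 0.06), COL1A1 (-0.42 ± 0.06) and FAP (-0.27 ± 0.07) fell (median -0.51, camera adjusted p = 0.0351; adjusted p = 0.120 with an estimated correlation), the call of FAP being lost without BPQD replicate 1 or 2 or control replicate 2. CDH5, the single endothelial marker measured, fell (-0.91 ± 0.14), and the single leukocyte marker, CD68, did not pass the test. All of these lists kept the same counts adjusted over the list alone.

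Stress pathways had single genes that changed without a list call. Of 24 NRF2 targets, 6 rose and 11 fell (8 and 11 adjusted over the list alone; camera adjusted p = 0.262): the cystine transporter SLC7A11 rose (0.67 ± 0.03), while AKR1C3 (-0.82 ± 0.06) and HMOX1 (-0.56 ± 0.04) fell. The chaperones of the endoplasmic reticulum HSP90B1 (0.56 ± 0.05) and HSPA5 (0.46 ± 0.01) rose, with 6 of 18 unfolded protein response genes higher and 1 lower (camera adjusted p = 0.0562). Of 21 p53 targets, 2 rose and 7 fell (3 and 9 adjusted over the list alone; camera adjusted p = 0.0880), CDKN1A, the p21 gene, from 24.6 ± 0.148 to 14.3 ± 0.137 FPKM (-0.74 ± 0.02). Of 14 heat shock chaperones 7 rose and 2 fell, and the list median was 0.12 while its mean was -0.02 (camera adjusted p = 0.117). Of 19 ATF4 targets 8 rose and 6 fell (camera adjusted p = 0.461). Of 11 NF-kB genes 5 rose and 2 fell (camera adjusted p = 0.256), with IL6 (0.82 ± 0.07) highest, and of 14 interferon-stimulated genes 4 rose and 4 fell (camera adjusted p = 0.792).

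The other lists were not called either. Cholesterol synthesis had 2 genes higher and 9 lower of 22 (median -0.17, camera adjusted p = 0.158), and fatty acid synthesis had 3 higher and 6 lower of 12 (camera adjusted p = 0.256). Of 23 genes of autophagy and lysosome 2 rose and 8 fell (median 0.05, test direction down, camera adjusted p = 0.850), and of 13 iron and ferroptosis genes none rose and 3 fell (median 0.04, test direction down, camera adjusted p = 0.581), among them GPX4 (-0.72 ± 0.03). Of 9 phosphate genes 1 rose and 3 fell (camera adjusted p = 0.235), and the phosphatase ALPP fell from 335 ± 1.16 to 175 ± 1.76 FPKM (-0.93 ± 0.02). Epithelial-mesenchymal transition had 1 gene higher and 5 lower of 15 (camera adjusted p = 0.267), the BCL2 family 1 higher and 4 lower of 16 (camera adjusted p = 0.310) with BMF lowest (-1.32 ± 0.14), and immediate early genes 1 higher and 5 lower of 13 (camera adjusted p = 0.165). Endocytosis had 1 higher and 6 lower of 18 (camera adjusted p = 0.123), and ribosomal proteins 4 higher and 7 lower of 23 (camera adjusted p = 0.259).

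**Figure D2:**
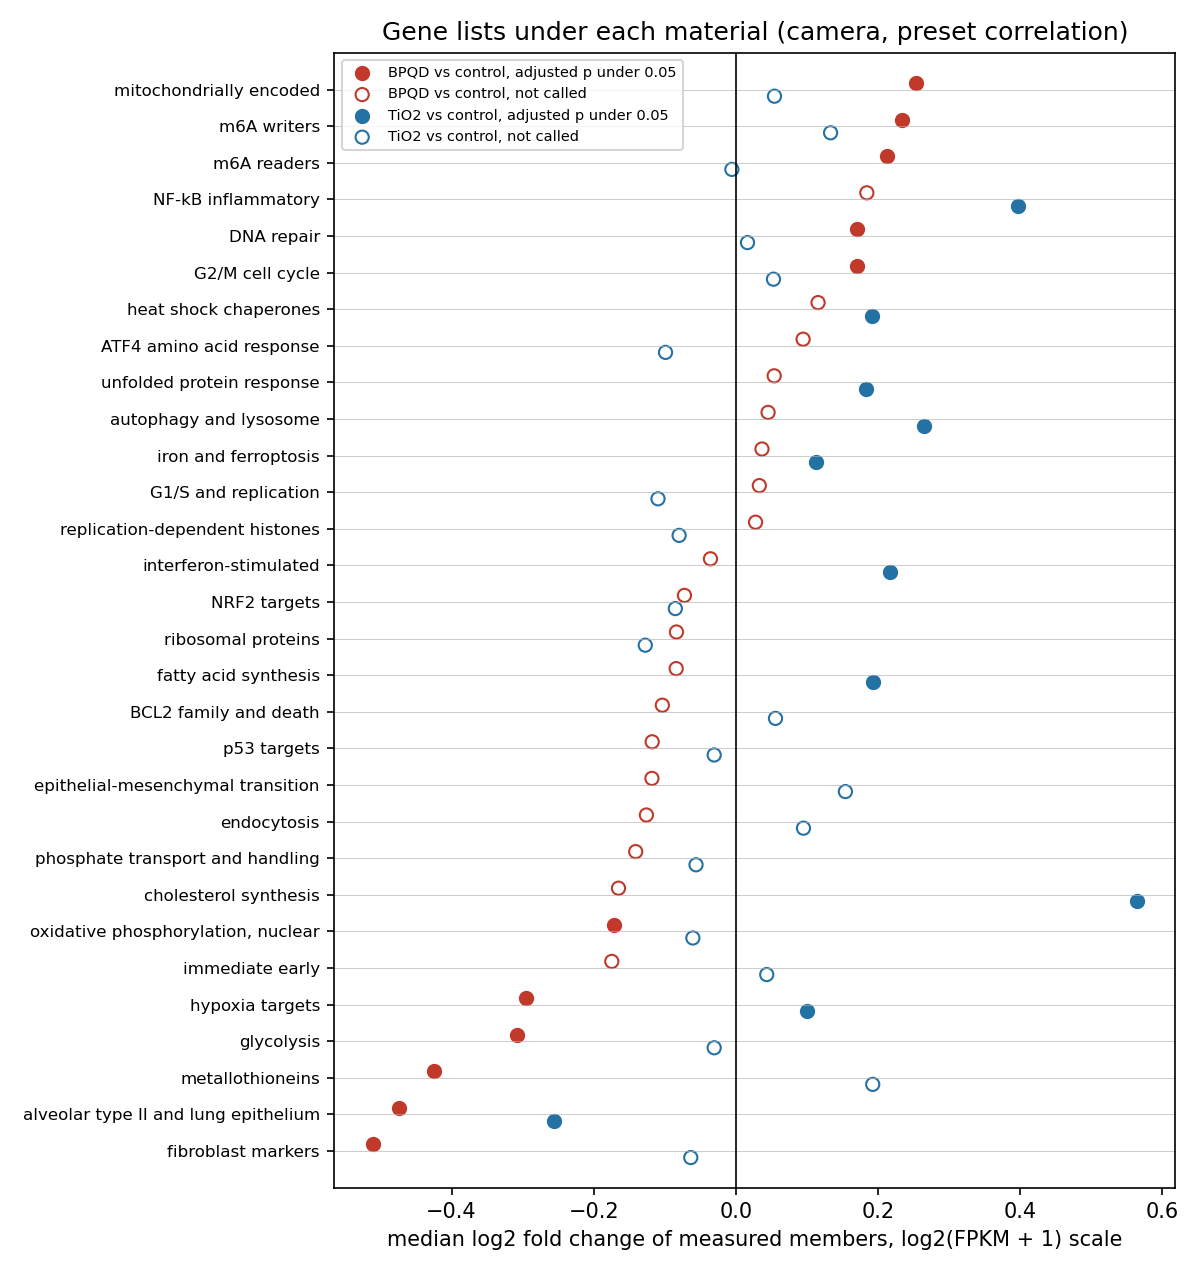
Median log2 fold change of the members of each gene list under BPQD and under TiO2, each against control, with the lists called by camera marked. Cholesterol synthesis has a median of 0.56 under TiO2, the largest among the lists with more than 4 members measured, and -0.17 under BPQD.

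TiO2 was compared with untreated cells in the same way. Of 22 genes of cholesterol synthesis 19 rose, and this list call held with an estimated correlation. The lists of autophagy and lysosome (10 of 23 genes higher), heat shock chaperones (8 of 14) and interferon-stimulated genes (8 of 14) were called higher as well. They were not called by camera with an estimated correlation (adjusted p = 0.0633, 0.0912 and 0.120). The same 3 polymerase III transcripts fell. The largest rise was in GPNMB (chromosome 7, 23235967 to 23275108), a lysosomal glycoprotein, at 7.63 ± 0.222 FPKM against 1.35 ± 0.144 (log2 fold change 1.88 ± 0.06, adjusted p = 1.14e-06). ACAT2 (chromosome 6, 159760328 to 159779055), which makes the acetoacetyl-CoA from which cholesterol synthesis starts, had 38.7 ± 0.0892 FPKM against 14.1 ± 0.479 (1.39 ± 0.03, adjusted p = 1.81e-07).

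Of 12224 genes, 4614 (37.7%) changed in limma, 2111 higher and 2503 lower. The median absolute log2 fold change was 0.25, and 40 genes changed by at least 1 on the log2 scale, 20 in each direction. The groups did not overlap in 6316 genes (51.7%), where chance gives 10%. The share of higher genes among the changed ones was 45.8%, 51.2% with median centring and 51.1% with quantile normalization. No balance between rises and falls is therefore read from these counts. The other large rises were CCN3 (1.32 ± 0.05), FABP3 (1.32 ± 0.05), RND3 (1.27 ± 0.06) and IL6, from 1.14 ± 0.0723 to 3.85 ± 0.233 FPKM (1.18 ± 0.07, adjusted p = 2.19e-05). RPPH1 (-2.50 ± 0.12), RN7SK (-2.34 ± 0.27) and RMRP (-2.33 ± 0.17) fell most, followed by ABHD14B (-1.66 ± 0.53), BCYRN1, also made by RNA polymerase III (-1.63 ± 0.22), SLC12A3 (-1.21 ± 0.02), BMF (-1.20 ± 0.14) and FBXO41 (-1.12 ± 0.29). The calls of ABHD14B and FBXO41 were lost in several of the other settings tried. ABHD14B had 16.6 FPKM in TiO2 replicate 2, but 3.18 in replicate 1 and 2.59 in replicate 3, so its fold depends on replicate 2.

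Of 22 genes of cholesterol synthesis, 19 rose and 1 fell over all genes and adjusted over the list alone. HMGCS1 (chromosome 5, 43287470 to 43313512), the synthase ahead of HMG-CoA reductase, had 34.8 ± 1.56 FPKM against 13.2 ± 0.312 (1.33 ± 0.06, adjusted p = 6.17e-06). MSMO1 (1.29 ± 0.05), IDI1 (1.18 ± 0.14) and SQLE (1.08 ± 0.04) rose by like amounts. The list median was 0.56 (camera adjusted p = 2.34e-10), and this list was called in the TiO2 comparison with an estimated correlation as well, at adjusted p = 0.0122. Of 12 genes of fatty acid synthesis 8 rose and 2 fell (8 and 3 adjusted over the list alone), including SCD from 59.1 ± 0.535 to 97.4 ± 0.642 FPKM (0.71 ± 0.02) and ACSS2 (0.80 ± 0.04), while the regulator SREBF1 fell (-0.34 ± 0.03). Their median was 0.19 (camera adjusted p = 0.00618; adjusted p = 0.118 with an estimated correlation).

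Of 23 genes of autophagy and lysosome, 10 rose and 2 fell (12 and 2 adjusted over the list alone). The protease CTSL rose from 80.4 ± 0.325 to 166 ± 1.69 FPKM (1.04 ± 0.02, adjusted p = 8.91e-08), while the autophagy kinase ULK1 fell (-0.69 ± 0.03). The list median was 0.26 (camera adjusted p = 0.000413; adjusted p = 0.0633 with an estimated correlation). CD68, a lysosomal protein and the single leukocyte marker measured, rose (0.73 ± 0.10). Of 13 iron and ferroptosis genes 4 rose and 1 fell (6 and 1 adjusted over the list alone), with ACSL4 (0.61 ± 0.03) and ACO1 (0.54 ± 0.03) higher. Their median was 0.11 (camera adjusted p = 0.0268; adjusted p = 0.104 with an estimated correlation), a call lost without TiO2 replicate 3.

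**Figure D3:**
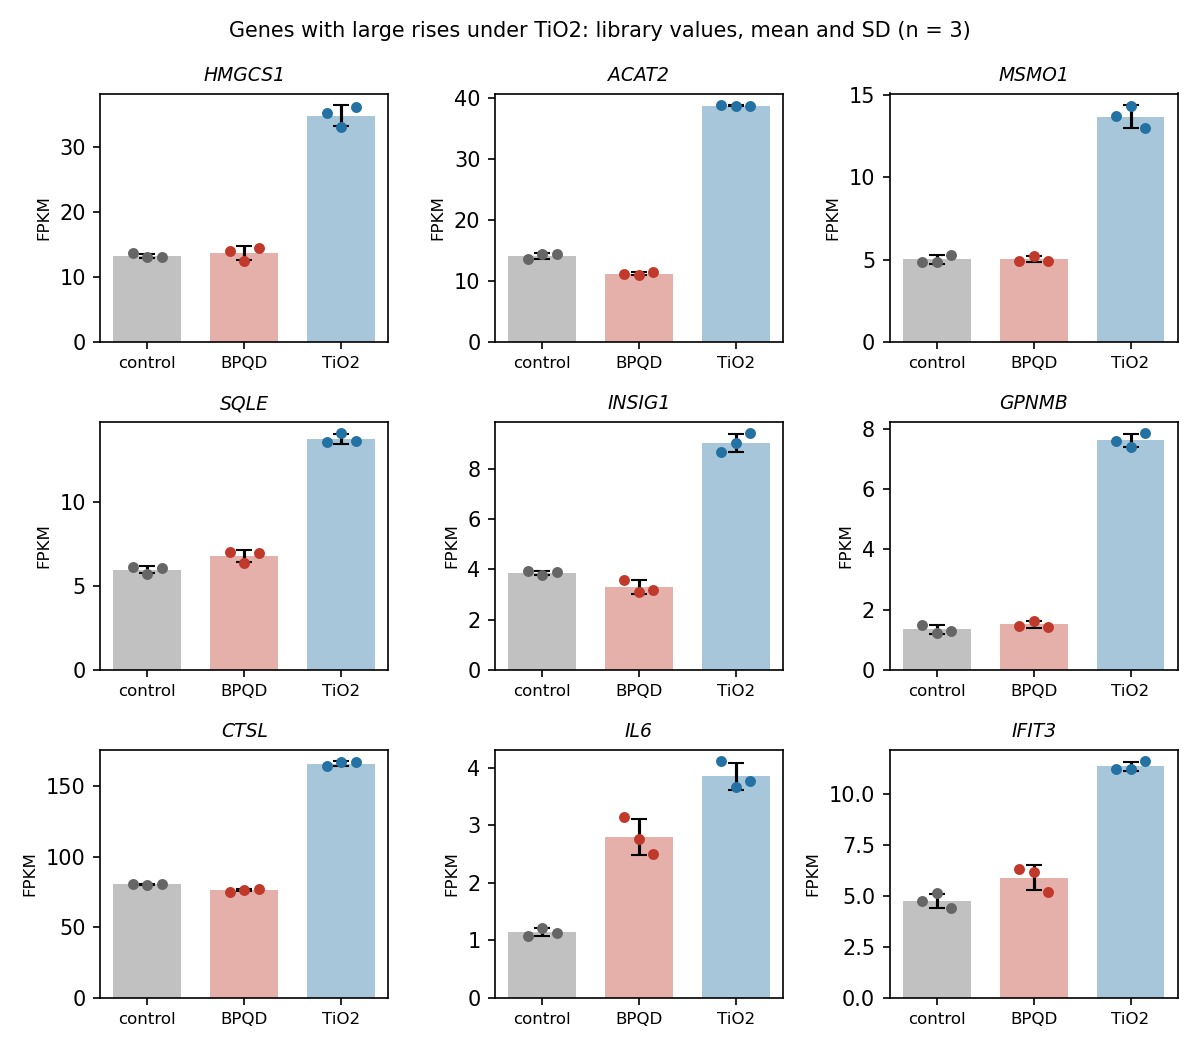
FPKM of 9 genes in the 9 input libraries; bars are group means, error bars SD (n = 3) and points single libraries. GPNMB had 7.63 FPKM under TiO2 against 1.35 in control and 1.51 in BPQD libraries, and HMGCS1 34.8 against 13.2 and 13.6.

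The lists of chaperones, NF-kB genes and interferon-stimulated genes were called higher by camera. Of 18 unfolded protein response genes 9 rose and none fell (10 and 0 adjusted over the list alone), including HSP90B1 (0.52 ± 0.05), HSPA5 (0.50 ± 0.01) and DNAJB11 (0.36 ± 0.02), with a median of 0.18 (camera adjusted p = 0.000580; adjusted p = 0.0633 with an estimated correlation). Of 14 heat shock chaperones 8 rose and 2 fell (9 and 3 adjusted over the list alone), HSP90AA1 by 0.54 ± 0.04 and HSPA8 by 0.47 ± 0.09 (median 0.19, camera adjusted p = 0.00914; adjusted p = 0.0912 with an estimated correlation). Of 11 NF-kB genes 7 rose and 1 fell, among them TNFAIP3 (0.52 ± 0.05) and ICAM1 (0.51 ± 0.03) beside IL6 (median 0.40, camera adjusted p = 0.00494; adjusted p = 0.0912 with an estimated correlation). Of 14 interferon-stimulated genes 8 rose and 2 fell (8 and 3 adjusted over the list alone), with IFIT3 at 11.3 ± 0.214 against 4.76 ± 0.349 FPKM (1.10 ± 0.07, adjusted p = 3.74e-05), IFIT2 (0.73 ± 0.06) and ISG15 (0.44 ± 0.06). Their median was 0.22 (camera adjusted p = 0.0261; adjusted p = 0.120 with an estimated correlation), and the call was lost without control replicate 1. Of 17 hypoxia targets 6 rose and none fell, ADM by 0.81 ± 0.19 and ANGPTL4 by 0.56 ± 0.09 (median 0.10, camera adjusted p = 0.0170; adjusted p = 0.0952 with an estimated correlation).

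Under TiO2 members of the m6A machinery went both ways, and neither the writers nor the readers were called as a list. METTL3 (0.15 ± 0.06, adjusted p = 0.0747), METTL14 (0.29 ± 0.11, adjusted p = 0.0740) and FTO (-0.30 ± 0.27, adjusted p = 0.418) did not pass the test, nor did WTAP (0.04 ± 0.04), VIRMA (0.04 ± 0.05), METTL16 (-0.07 ± 0.08), RBM15 (0.18 ± 0.19) and CBLL1 (0.88 ± 0.35). METTL14 passed in 2 of the other settings, among them quantile normalization, METTL3 without TiO2 replicate 3, and RBM15 without TiO2 replicate 2. ZC3H13 (0.12 ± 0.03), METTL5 (0.25 ± 0.07) and ZCCHC4 (0.21 ± 0.06) rose, and PCIF1 (-0.26 ± 0.04), RBM15B (-0.11 ± 0.03) and ALKBH5 (-0.19 ± 0.03) fell. The call of METTL5 was lost in 6 of the other settings, that of ZCCHC4 in 4 and that of RBM15B in 1. The writers thus had 3 genes higher and 2 lower of 12 (camera adjusted p = 0.256). Of 15 readers 4 rose and 3 fell (median -0.01, camera adjusted p = 0.831), with YTHDC1 higher (0.28 ± 0.08) and PRRC2A (-0.37 ± 0.03) and IGF2BP1 (-0.30 ± 0.03) lower. The call of YTHDC1 under TiO2 was lost in 8 of the other settings, among them the fits without any 1 of the TiO2 replicates. YTHDC2 (0.03 ± 0.03), YTHDF1 (-0.04 ± 0.03), YTHDF2 (-0.14 ± 0.47) and YTHDF3 (-0.35 ± 0.46) did not pass.

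The epithelial genes KRT18 (-0.28 ± 0.02), KRT7 (-0.23 ± 0.03), MUC1 (-0.20 ± 0.04) and ABCA3 (-0.50 ± 0.03) fell (median -0.26, camera adjusted p = 0.00378; adjusted p = 0.104 with an estimated correlation). Of the 4 fibroblast genes FAP rose and COL1A1 and PDGFRB fell (camera adjusted p = 0.635). MT2A (0.19 ± 0.02) and MT1X (0.21 ± 0.03) rose and MT1E fell (-0.08 ± 0.02), without a call for the metallothioneins (camera adjusted p = 0.256); the call of MT1E was lost in 2 of the other settings, among them quantile normalization. Of 24 NRF2 targets 6 rose and 10 fell (8 and 10 adjusted over the list alone; camera adjusted p = 0.679), and of 21 p53 targets 4 rose and 10 fell (camera adjusted p = 0.242), with GDF15 (0.48 ± 0.06) higher and BTG2 (-0.72 ± 0.04) lower. The 19 ATF4 targets had 4 higher and 6 lower (camera adjusted p = 0.667), G2/M 5 and 5 of 22 (camera adjusted p = 0.198), G1/S and replication 6 and 8 of 22 (6 and 10 adjusted over the list alone; camera adjusted p = 0.303), and DNA repair 3 and 3 of 18 (camera adjusted p = 0.667). Glycolysis had 2 higher and 3 lower of 18 (camera adjusted p = 0.864), oxidative phosphorylation 5 and 6 of 23 (camera adjusted p = 0.832), mitochondrially encoded mRNAs 0 and 1 of 13 (camera adjusted p = 0.792) and histones 0 and 1 of 11.

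Further lists under TiO2 were not called. Ribosomal proteins had 4 genes higher and 9 lower of 23 (camera adjusted p = 0.230), and epithelial-mesenchymal transition 5 and 1 of 15 (camera adjusted p = 0.110). Immediate early genes had 5 higher and 2 lower of 13 (camera adjusted p = 0.123), among them FOSL1 (0.80 ± 0.11), IER3 (0.67 ± 0.04) and JUN (0.60 ± 0.05). The BCL2 family had 4 higher and 3 lower of 16 (camera adjusted p = 0.490), endocytosis 5 and 6 of 18 (camera adjusted p = 0.703), and phosphate handling 3 and 2 of 9 (median -0.06, mean 0.00). ALPP fell (-0.42 ± 0.02).

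The materials were then compared with each other, at their different doses, as a direct test of where the exposures differed. The list of cholesterol synthesis was called lower under BPQD than under TiO2, also with an estimated correlation. The lists of autophagy and lysosome, hypoxia, metallothioneins and interferon-stimulated genes were called lower, and those of m6A readers, G2/M, G1/S and DNA repair higher. None of these 8 held with an estimated correlation (adjusted p = 0.0633 to 0.104). HOXC8 (chromosome 12, 54008985 to 54012769), a homeobox factor, had 7.44 ± 0.152 FPKM under BPQD and 1.39 ± 0.0933 under TiO2 (log2 fold change 1.82 ± 0.05, adjusted p = 1.78e-06). ACAT2 had 11.2 ± 0.262 against 38.7 ± 0.0892 (-1.70 ± 0.03, adjusted p = 1.06e-07) and GPNMB 1.51 ± 0.111 against 7.63 ± 0.222 (-1.78 ± 0.06).

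In limma 4596 of 12224 genes (37.6%) differed, 2323 higher and 2273 lower under BPQD, 89 of them by at least 1 on the log2 scale, and the groups did not overlap in 6250 genes (51.1%; chance gives 10%). The share of higher genes among those that differed was 50.5%, 60.5% with TPM and 61.5% with no filter, so no balance is read from these counts. LINC02595 (1.85 ± 0.09), CASC19 (1.69 ± 0.25), LINC00641 (1.54 ± 0.06) and NEAT1 (1.43 ± 0.31) were higher under BPQD, as were SCARNA12 (2.05 ± 0.46), UPK3BL1 (2.02 ± 0.59) and SENP3-EIF4A1 (1.34 ± 0.43). GPX1 had 34.2 ± 8.52 against 163 ± 71.6 FPKM (-2.12 ± 0.35), and FABP3 (-1.67 ± 0.05), ANGPTL4 (-1.40 ± 0.09), IGFL2-AS1 (-1.36 ± 0.05), SERINC2 (-1.36 ± 0.05) and PSCA (-1.35 ± 0.03) were lower. GPX1 had 80.0 FPKM in TiO2 replicate 1, but 204 in replicate 2 and 204 in replicate 3, so the size of its fold depends on replicate 1. The calls of SENP3-EIF4A1 and UPK3BL1 were lost in several of the other settings tried.

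Of the 30 lists tested, 5 were higher and 15 lower under BPQD than under TiO2. Of 22 genes of cholesterol synthesis 1 was higher and 20 lower (median -0.80, camera adjusted p = 3.74e-11), a call that held with an estimated correlation (adjusted p = 0.0122), with HMGCS1 (-1.29 ± 0.06), MSMO1 (-1.28 ± 0.05) and INSIG1 (-1.23 ± 0.05) among them. Hypoxia targets had 1 higher and 11 lower of 17 (1 and 12 adjusted over the list alone; median -0.40, camera adjusted p = 0.000413; adjusted p = 0.0633 with an estimated correlation), including ADM (-1.24 ± 0.19). Of 23 genes of autophagy and lysosome 11 were lower, CTSL (-1.11 ± 0.02) among them. Their median was -0.35 (camera adjusted p = 0.000771, and adjusted p = 0.0633 with an estimated correlation). Of 12 fatty acid genes 6 were lower, among them ACSS2 (-1.15 ± 0.04) and SCD (-0.82 ± 0.02), with a median of -0.14 (camera adjusted p = 0.000906; adjusted p = 0.0912 with an estimated correlation). All 3 metallothioneins were lower (MT1E not with quantile normalization), with MT1X at -0.71 ± 0.03 (median -0.62, camera adjusted p = 0.00321; adjusted p = 0.0867 with an estimated correlation). Of 14 interferon-stimulated genes 1 was higher and 8 lower, with IFIT3 at -0.85 ± 0.07 (median -0.25, camera adjusted p = 0.00660; adjusted p = 0.0952 with an estimated correlation).

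Of 15 m6A readers 10 were higher under BPQD and 1 lower (median 0.21, camera adjusted p = 0.00135; adjusted p = 0.103 with an estimated correlation), with RBMX (0.42 ± 0.03), IGF2BP1 (0.34 ± 0.03), YTHDC1 (0.32 ± 0.08), YTHDC2 (0.21 ± 0.03) and YTHDF1 (0.09 ± 0.03) higher and IGF2BP2 lower (-0.44 ± 0.05). The call of YTHDF1 was lost in 6 of the other settings. Of 12 writers 4 were higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.123), METTL16 by 0.37 ± 0.08, while METTL3 (0.07 ± 0.06, adjusted p = 0.396) and METTL14 (0.26 ± 0.11, adjusted p = 0.0948; passed without TiO2 replicate 2) did not pass; neither eraser differed. G2/M genes had 11 higher and 1 lower of 22, MKI67 by 0.38 ± 0.04 (camera adjusted p = 0.00378; adjusted p = 0.0912 with an estimated correlation). G1/S and replication had 10 higher and 3 lower of 22 (11 and 3 adjusted over the list alone), MCM7 by 0.35 ± 0.02 (camera adjusted p = 0.0194; adjusted p = 0.104 with an estimated correlation). DNA repair had 8 higher and none lower of 18, FANCD2 by 0.35 ± 0.05 (camera adjusted p = 0.00442; adjusted p = 0.104 with an estimated correlation), and mitochondrially encoded mRNAs 6 higher and none lower of 13, MT-CYB by 0.48 ± 0.06 (camera adjusted p = 0.0193; adjusted p = 0.351 with an estimated correlation).

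The remaining called lists were all lower under BPQD. Oxidative phosphorylation had 11 of 23 genes lower (camera adjusted p = 0.00259; adjusted p = 0.0867 with an estimated correlation), and glycolysis 7 lower and 1 higher of 18, with SLC2A1 at -0.58 ± 0.03 (camera adjusted p = 0.00378; adjusted p = 0.0930 with an estimated correlation). Iron and ferroptosis (6 of 13 lower), epithelial-mesenchymal transition (5 of 15) and immediate early genes (6 of 13, IER3 at -1.18 ± 0.04) had no gene higher, with camera adjusted p of 0.00378, 0.00366 and 0.00378, each with adjusted p = 0.0867 with an estimated correlation. NF-kB genes (6 of 11 lower) had a camera adjusted p of 0.0103 and adjusted p = 0.0930 with an estimated correlation. Phosphate handling (6 of 9 lower) and endocytosis (2 higher and 7 lower of 18; 3 and 11 adjusted over the list alone) each had a camera adjusted p of 0.0261 and adjusted p = 0.104 with an estimated correlation. The BCL2 family (8 of 16 lower) had a camera adjusted p of 0.0247 (adjusted p = 0.125 with an estimated correlation), lost without BPQD replicate 1.

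In the comparison of the materials 10 lists were not called. NRF2 targets had 6 genes higher and 9 lower of 24 (camera adjusted p = 0.381), with HMOX1 lower (-0.72 ± 0.04), ATF4 targets 7 and 4 of 19 (camera adjusted p = 0.330) and p53 targets 3 and 7 of 21 (median 0.04, mean -0.05, camera adjusted p = 0.560). Heat shock chaperones had 2 higher and 6 lower of 14 (camera adjusted p = 0.149), the unfolded protein response 0 and 5 of 18 (camera adjusted p = 0.123), histones 3 and 2 of 11 (camera adjusted p = 0.448) and ribosomal proteins 2 and 1 of 23 (camera adjusted p = 0.831). Of 4 epithelial genes 1 was higher and 3 lower (camera adjusted p = 0.172), and of 4 fibroblast genes likewise 1 and 3 (camera adjusted p = 0.238). CD68 (-0.70 ± 0.10) and CDH5 (-0.75 ± 0.14) were lower.

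Many genes differed from control in the same direction under both materials. Of the genes called in both comparisons with control, 2574 went the same way, 1141 higher and 1433 lower in both, and 436 went opposite ways. Independent lists of these sizes would share 436 higher, 586 lower and 1011 opposite genes. Because both comparisons use the same 3 control libraries, groups that do not differ also give similar fold changes: the correlation across genes was 0.485 and averaged 0.493 in 100 simulations of unchanged groups. The covariance was 0.0406 against 0.0115 simulated (highest 0.0157), and the simulations called a mean of 0.01 genes in both comparisons. Genes are not independent replicates, and the controls were too few to give each comparison its own. Controls that differ as a group from both exposures would give the same pattern, and the simulations do not cover that. A response common to the materials is therefore not established. BTG2, KRT18, RN7SK, RMRP and RPPH1 fell and SLC7A11, HSPA5 and IL6 rose under both materials.

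The m6A libraries were compared through the authors' deposited tables of differential peaks, which give a fold and a p per peak but no value per library, so no error between replicates can be given. Under BPQD, peaks in the noncoding RNAs MALAT1 and NEAT1 were higher than in control, and more peaks were higher than lower. The table from the authors, as deposited, held 14903 peaks in 9480 genes, of which 9661 had a differential p under 0.05: 5616 higher (58.1%) and 4045 lower. At an absolute log2 fold of at least 1 there were 1361, 1005 of them higher. Peaks are not replicates, and no library values stand behind these counts. The share of higher peaks fell from 68.3% in the lowest of 10 bins of mean FPKM to 23.9% in the highest. Under TiO2 it fell from 79.4% to 32.2%. No general gain of m6A is therefore read from the counts of either material.

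In the authors' deposited table, MALAT1 (chromosome 11, 65502416 to 65503134, exon) had a peak with a log2 fold change of 1.42, and NEAT1 had peaks of 0.174 (chromosome 11, 65422774 to 65425496) and 3.81 (65428191 to 65428791). BTBD2 (chromosome 19, 1988166 to 1990330) and FBXO22 (chromosome 15, 75937514 to 75941284) had 1.81 and 1.26 in the authors' deposited table. Lower peaks in the authors' deposited table were those of EIF3C (chromosome 16, 28688768 to 28720663, log2 fold change -2.42), RPL19 (chromosome 17, 39204186 to 39204732, -0.411), NCL (chromosome 2, 231460506 to 231461821, -0.284), HNRNPA2B1 (chromosome 7, 26192249 to 26196576, -0.194) and FTH1 (chromosome 11, 61967041 to 61967634, -0.189). EIF3C has a near-identical neighbouring copy, so its reads cannot be placed with certainty. METTL3 had a higher peak annotated to its 5' UTR (chromosome 14, 21510900 to 21511342) with a log2 fold change of 0.637 in the authors' deposited table. By list, the deposited table by the authors held 13 higher and 1 lower peaks in 8 writer genes and 6 higher and 11 lower in 10 reader genes. The mitochondrially encoded mRNAs had 8 peaks, all lower, the metallothioneins 3, all lower, and the ribosomal proteins 1 higher and 6 lower; ALKBH5 had a lower peak (-0.259) in the authors' deposited table. The share of higher peaks falls with expression level, and from the shares in their bins of expression 8.59 of the 14 writer peaks and 7.82 of the 17 reader peaks would be higher. The bins give 3.16 of 8 for the mitochondrially encoded mRNAs, 0.717 of 3 for the metallothioneins and 1.67 of 7 for the ribosomal proteins, and no test was run by list.

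**Figure D4:**
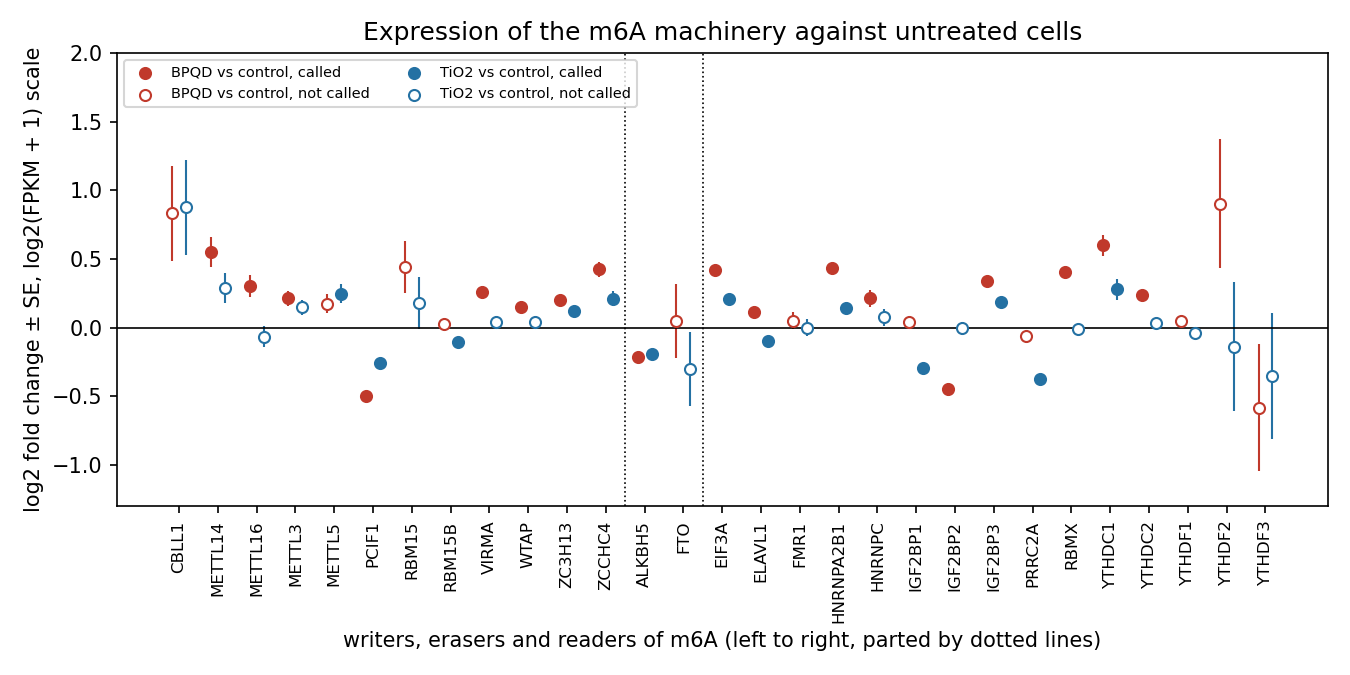
Log2 fold change of input expression for the listed m6A writers, erasers and readers under BPQD and TiO2 against control. Points are limma estimates and bars their SE (n = 3 libraries per group). METTL14 stands at 0.55 under BPQD and 0.29 under TiO2, YTHDC1 at 0.60 and 0.28, and ALKBH5 at -0.21 and -0.19.

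In the authors' deposited tables the share of higher peaks at p under 0.05 was larger under TiO2 than under BPQD, and at an absolute log2 fold of at least 1 it was smaller (60.0% against 73.8%). The authors' deposited table held 12891 peaks in 8706 genes, 8258 of them with a differential p under 0.05: 5193 higher (62.9%) and 3065 lower. At an absolute log2 fold of at least 1 there were 707, 424 of them higher. MYC (chromosome 8, 127738310 to 127741453, annotated by the authors as 5' UTR) had a log2 fold change of 0.286 in the authors' deposited table. RPL19 (-0.407), RPL26 (-0.245) and GNAS (chromosome 20, 58910982 to 58911192, -0.452) were lower in the authors' deposited table. SHLD2P1 (2.66), MSTO1 (4.62), RANBP2 (0.336), BOLA2B (-7.99) and EIF3C (-1.44) also had peaks among the smallest p in the authors' deposited table, and each has near-identical copies elsewhere. Writers had 10 higher peaks and 1 lower, with METTL3 at 0.616 in the authors' deposited table, readers 7 and 6, mitochondrially encoded mRNAs 3 and 0, and metallothioneins 0 and 3, where the bins of expression give 7.18, 6.10, 1.60 and 0.966 higher peaks. FTO had a lower peak (-0.334) in the authors' deposited table.

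The annotated position of the changed peaks differed between the materials. Each peak has 1 position, taken from the authors' annotation. Peaks had median widths of 658 and 789 bases and can span several regions, so this position need not be where the signal changed. The exon class also holds noncoding RNAs such as MALAT1. Under BPQD 54.4% of 2459 differential peaks at the 5' UTR were lower, against 34.0% of 2373 in exons and 39.3% of 4829 at the 3' UTR. Under TiO2 the shares were 34.3% of 2277, 35.0% of 1691 and 39.4% of 4290. The odds of a lower rather than a higher peak were thus 1.98 times as high at the 5' UTR as elsewhere under BPQD (95% interval 1.81 to 2.17, Fisher's exact test over peaks, p = 8.45e-48) and 0.845 times under TiO2 (0.764 to 0.935, p = 0.00110). The ratio of these odds ratios was 2.35 (2.05 to 2.69). All of these intervals treat peaks as independent, and that of the ratio also treats the materials as independent, although they share control libraries. No spread between libraries enters them.

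**Figure D5:**
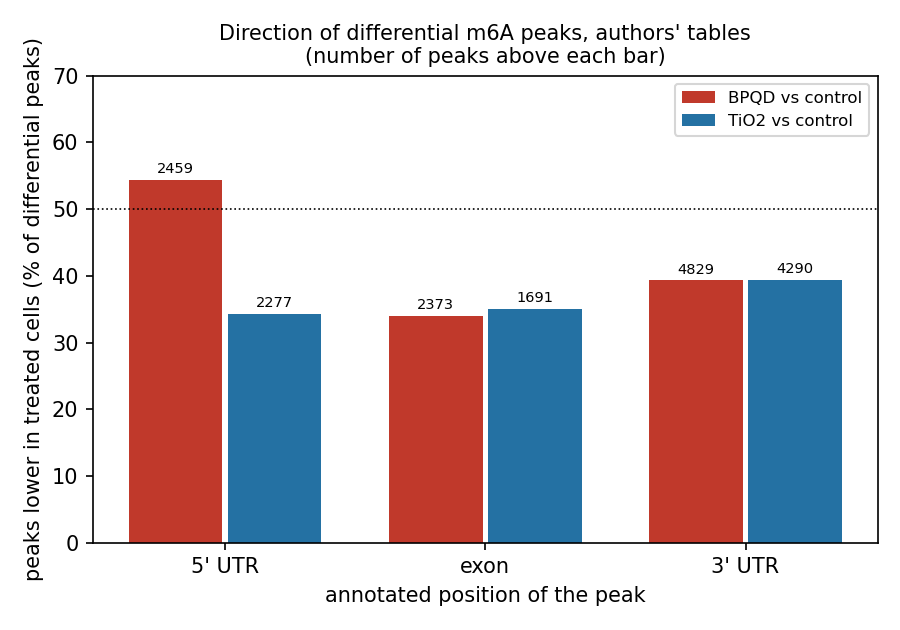
Percent of the authors' differential peaks (p under 0.05) that were lower than in control, by annotated position and material, with the number of peaks above each bar. At the 5' UTR 54.4% were lower under BPQD and 34.3% under TiO2.

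Many peaks changed the same way under both materials. Of 9661 differential peaks under BPQD, 4668 overlapped one under TiO2 by at least 1 base. Of these BPQD peaks 4331 overlapped a TiO2 peak of the same direction and 417 one of the opposite direction. Some BPQD peaks overlapped both kinds and count in both. Peaks are given by outer limits that can run across introns, up to 1316931 bases. With a mutual overlap of at least 0.5 of each length, 3933 BPQD peaks overlapped one of the same direction and 227 one of the opposite direction. The tables share their control libraries, and no simulation could be run without values per library.

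Peak change was set against expression change in the same genes, with 1 peak per gene. Under BPQD, expression was higher in 54.0% of genes with a higher peak and in 43.3% of genes with a lower one (odds ratio 1.54, 95% interval 1.39 to 1.70, Fisher's exact test over genes, p = 5.24e-18). Under TiO2 the odds ratio was 1.01 (0.911 to 1.13, Fisher's exact test over 6094 genes, p = 0.807). Both use the expression ratio in the authors' deposited tables. The peak fold is a change of enrichment relative to input of the same cells, so peak and expression change are not independent. The share of higher peaks also falls with expression level, and these odds ratios were not pooled over that level. No link between methylation and expression is read from them. Against the limma fold changes of the genes tested for expression, the odds ratio was 1.65 under BPQD (1.48 to 1.84, Fisher's exact test over 5332 genes, p = 2.75e-19) and 1.18 under TiO2 (1.05 to 1.33, Fisher's exact test over 4883 genes, p = 0.00594). Among peaks with an absolute log2 fold of at least 1 the odds ratio was 1.03 under BPQD and 0.487 under TiO2, so these relations rest on the choice of peaks.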

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

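The tests of the control libraries, of RNA without a poly(A) tail and of polymerase III transcripts with BCYRN1 were chosen only after the results were seen, and so were the settings behind the tests of expression level, of uncalled genes and of gene span; the other tests in this part were fixed before their results were seen.

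The annotated position of changed m6A peaks differed between the materials, although a peak can span more than its annotated region. The odds ratio of a lower peak at the 5' UTR under BPQD was 2.35 times that under TiO2 (95% interval 2.05 to 2.69). This interval treats peaks and materials as independent, although the materials share control libraries, and holds no spread between libraries. Pooled over 10 bins of expression level the BPQD odds ratio was 1.77, and in genes whose expression was not called it was 2.14, which argues against expression level or expression change as the whole cause. The TiO2 table, which uses the same control libraries, had an odds ratio of 0.845, which argues against those libraries alone. A change in the BPQD immunoprecipitation itself, such as RNA fragment size or antibody yield, may explain the pattern as well as a change of methylation, and no value per library was at hand to test it. A biological difference at 5' UTRs under BPQD remains a hypothesis.

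RN7SK, RMRP and RPPH1 fell by more than 2 on the log2 scale under both materials. If all RNA without a poly(A) tail had been captured less, histone, snoRNA, scaRNA and spliceosomal snRNA genes would be due to fall too. The lower of their median log2 fold changes under the materials was -0.0705 (105 genes), which argues only against an equal loss across those genes. Among 495 other genes of short span it was -0.13, which argues against the handling of short genes in general. Among 4 other RNA polymerase III transcripts it was -0.30, and -0.33 with BCYRN1, which had been left out because its value was known, and this argues only against an equal loss of all of them. BCYRN1 fell under both materials (-0.88 ± 0.22 and -1.63 ± 0.22), and only 1 of the other 4 has the external promoter type of the 3 genes. A loss of some polymerase III transcripts may therefore still apply, as may an untested removal of these RNAs along with ribosomal RNA. The share of the genes like ribosomal RNA that were picked by clone name was also lower under both materials, while total ribosomal RNA was not measured.

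The gene lists called under BPQD could follow a trend with gene span or with expression level rather than the functions of the genes. With the span trend taken out of each library 11 of the 11 lists were called in the same direction and 2 more were gained, and with the expression level trend taken out also 11 and 1 more, which argues against both trends as the whole cause. Camera called 0 of these lists with an estimated correlation, while 9 of all lists tested had an unadjusted p under 0.05. The estimate was below the preset 0.01 for m6A writers (-0.041), metallothioneins (-0.050), hypoxia targets (-0.033), oxidative phosphorylation (-0.0064) and fibroblast genes (-0.149). Correlation between members therefore does not account for the loss of these calls. It stays open for the other called lists, with estimates above 0.01, up to 0.334 for mitochondrially encoded mRNAs. The simulated list, of independent genes, also weakened in this setting (camera adjusted p = 0.00159 in place of 8.73e-26). An effect of the exposure and a difference between the cultures of a group cannot be separated with these labels, and no biological explanation was tested.

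Lists were singled out where the medians against control had opposite signs under the materials, at least 1 of these was called, and the direct test of BPQD against TiO2 was called. Only the hypoxia targets were called against control under both materials, so opposite responses are not read from the other lists. The readers had a median of -0.01 under TiO2 (camera adjusted p = 0.831), and the interferon-stimulated genes -0.04 under BPQD (camera adjusted p = 0.792). The m6A readers had a median log2 fold change of 0.21 in that direct test. The metallothioneins had -0.62, with all 3 genes lower under BPQD. The interferon-stimulated genes had a median of -0.25. The hypoxia targets had a median of -0.40. Cholesterol synthesis had a median of -0.80, the only one of these called with an estimated correlation (adjusted p = 0.0122). Fatty acid synthesis had a median of -0.14.

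Other groupings of the libraries were fitted in the same way. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05; in each comparison only 1 split, the real one, gave a count as high as its own. For BPQD against control the real split called 5384 genes and 11 lists and the highest other 6 genes and 5 lists. For TiO2 against control the counts were 4614 genes and 10 lists against 5 and 4, and for BPQD against TiO2 4596 genes and 20 lists against 4 and 6. For genes called in both comparisons with control in the same direction, 1 of 100 drawn regroupings of the 9 libraries, the real one, reached 2574. The highest other gave 1289, which argues against a random grouping of these libraries. Regrouping breaks every difference between the groups. It therefore cannot tell a response to both materials from controls that differ as a group.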

How the results depend on the processing

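The settings without genes like ribosomal RNA, with the gene span or expression level trend removed, and for peak positions were chosen only after the data were seen; all other alternatives, the gene lists and the rule for named genes were fixed before the data were examined.

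No named gene or list was called in the opposite direction in any setting tried. Among the genes called for BPQD against control 2 were called the opposite way after quantile normalization, 1 for TiO2 against control and 1 for BPQD against TiO2. With the preset correlation, 27 of 30 lists kept their side of the threshold in every setting tried on lists for BPQD against control, also without a library of the third group, 28 for TiO2 against control and 29 for BPQD against TiO2. Of the genes that meet the naming rule, 118 of 147, 118 of 137 and 123 of 147 did. Leaving out BPQD replicate 1 or control replicate 1 ended the call of the hypoxia targets for BPQD against control (adjusted p = 0.0797 and 0.0806), as did leaving out TiO2 replicate 2 or 3 (adjusted p = 0.0509 and 0.0530). Without control replicate 1 the interferon-stimulated genes were not called for TiO2 against control (adjusted p = 0.0518), nor were the iron genes without TiO2 replicate 3 (adjusted p = 0.0613). The BCL2 family was not called for BPQD against TiO2 without BPQD replicate 1 (adjusted p = 0.0668). The unfolded protein response was called for BPQD against control without BPQD replicate 3 (adjusted p = 0.0448) or control replicate 3 (adjusted p = 0.0325), without TiO2 replicate 2 (adjusted p = 0.0421), and with the span or expression level trend removed (adjusted p = 0.0201 and 0.0474). Endocytosis was called for BPQD against control with the span trend removed (adjusted p = 0.0493). With an estimated correlation 0 lists were called for BPQD against control, 1 for TiO2 against control and 1 for BPQD against TiO2, in place of 11, 10 and 20. This setting also weakened the call of a simulated list of independent genes (camera adjusted p = 0.00159 in place of 8.73e-26). Fewer calls therefore do not by themselves point to correlated members. At an unadjusted p under 0.05 camera gave 9, 10 and 18 with an estimated correlation.

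Raising the filter to a mean of at least 5 FPKM left 6504 genes to test, and 3495 changed for BPQD against control, 3171 for TiO2 against control and 2832 for BPQD against TiO2, fewer because fewer genes were tested. With no filter, 36576 genes were tested and 5984, 3902 and 5571 changed. Over all settings that kept every library, the counts ran from 3495 to 5984, from 3171 to 4635 and from 2832 to 5571. Rescaled to TPM, 58.3% of the genes changed by BPQD were higher in place of 46.9%, and 56.1% without genes like ribosomal RNA; for BPQD against TiO2 the share was 60.5% with TPM and 61.5% with no filter in place of 50.5%. At adjusted p under 0.01, 1469 genes in place of 2574 were called in both comparisons with control in the same direction, the stricter threshold being the cause.

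Leaving out 1 library of the groups compared at a time gave 4690 to 4781 genes for BPQD against control, 3754 to 4005 for TiO2 against control and 3923 to 3989 for BPQD against TiO2. It gave 10 to 12, 9 to 10 and 19 to 20 lists, and 2085 to 2321 genes shared by the materials. The group left with fewer libraries is assumed to vary like the others.

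With the replicate block, 4996, 4160 and 4150 genes changed, 11, 10 and 20 lists were called and 2258 genes were shared. The replicate numbers do not pair the samples: after group means were removed, libraries with the same number correlated at -0.08 to 0.07, and 3 of the 9 libraries had their best partner at their own number.

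The peak counts follow the threshold by construction. In the authors' deposited tables there were 9661 differential peaks under BPQD and 8258 under TiO2 at p under 0.05. Of the BPQD peaks 4331 overlapped a TiO2 peak of the same direction. Under BPQD the authors' deposited table held 4197 at p under 0.001, 6520 at an FDR under 0.05 and 1361 at an absolute log2 fold of at least 1. Under TiO2 the authors' deposited table held 3435 at p under 0.001, 5153 at an FDR under 0.05 and 707 at an absolute log2 fold of at least 1. At p under 0.001, 1677 BPQD peaks in the authors' deposited tables overlapped a TiO2 peak of the same direction. Among peaks with an absolute log2 fold of at least 1 the odds ratio between peak and expression change in the authors' deposited tables was 1.03 under BPQD in place of 1.54, and 0.487 under TiO2 in place of 1.01; the cause was not tested. The depth of the libraries is unknown, so what it limits cannot be said.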

Other observations

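The pathway tests in this part and the levels known for A549 were chosen only after the data were seen. Sets were taken from the KEGG annotation of the deposited table, with long noncoding RNA genes added, and tested with camera (201 sets, adjusted over 603 tests). With an estimated correlation camera called 0, while 62 sets for BPQD against control, 26 for TiO2 against control and 78 for BPQD against TiO2 had an unadjusted p under 0.05. The genes named here were also chosen after their values were seen.

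Of the sets called under BPQD most were lower, while sets of ribosome biogenesis and RNA processing were higher and the ribosome set lower. Of 72 genes of ribosome biogenesis 39 rose and 8 fell (median log2 fold change 0.21, camera adjusted p = 6.53e-06; adjusted p = 0.108 with an estimated correlation), including the small subunit factors WDR43 (0.63 ± 0.02) and WDR3 (0.58 ± 0.03) and the snoRNP core protein NOP58 (0.52 ± 0.03). Under TiO2 33 of these genes rose and 11 fell (median 0.12, camera adjusted p = 0.00327; adjusted p = 0.108 with an estimated correlation). Of 130 genes of the KEGG ribosome set 20 rose and 45 fell under BPQD (median -0.11, camera adjusted p = 0.0239; adjusted p = 0.108 with an estimated correlation). Of 130 spliceosome genes 54 rose and 16 fell under BPQD (median 0.09, camera adjusted p = 0.00528; adjusted p = 0.108 with an estimated correlation), with HNRNPA1 (0.73 ± 0.03) and SRSF2 (0.53 ± 0.11) higher. Of 43 aminoacyl-tRNA synthesis genes 21 rose and 7 fell (median 0.13, camera adjusted p = 0.0163; adjusted p = 0.108 with an estimated correlation), with FARSB (0.43 ± 0.02) higher. Of 435 long noncoding RNA genes 121 rose and 48 fell under BPQD (median 0.09, camera adjusted p = 0.0145; adjusted p = 0.108 with an estimated correlation), while under TiO2 30 rose and 73 fell, and between the materials 148 were higher and 35 lower under BPQD.

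For BPQD against control 47 sets were called (7 up and 40 down), 20 for TiO2 against control (15 up and 5 down) and 63 for BPQD against TiO2 (6 up and 57 down). The highest counts in other splits of the libraries were 17, 5 and 10, and in each comparison only 1 of the 10 splits, the real one, reached its count; 10 splits are too few for a share under 0.05.

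The sets of the cell cycle (36 rose and 22 fell of 117), DNA replication, mismatch repair and nucleotide excision repair were not called for BPQD against control (camera adjusted p = 0.102, 0.167, 0.160 and 0.164). Among the lower sets were calcium signaling (5 rose and 32 fell of 73, median -0.17, camera adjusted p = 0.00663; adjusted p = 0.108 with an estimated correlation) and oxidative phosphorylation (15 rose and 48 fell of 117, median -0.12, camera adjusted p = 0.0111; adjusted p = 0.108 with an estimated correlation).

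The share of higher peaks fell with the expression of the gene in the authors' deposited tables. Under BPQD it was 68.3% in the lowest of 10 bins of mean FPKM and 23.9% in the highest, and under TiO2 79.4% and 32.2%.

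CDKN2A and CDKN2B, which are lost by homozygous deletion in A549, were present in all 9 input libraries, the lowest value of either gene being 7.12 FPKM. This value speaks against cells that all carry that deletion, and a candidate explanation is that the cells sequenced were not A549 or were mixed with other cells. In A549 AKR1B10 and AKR1C1 are abundant, and here they stayed at or below 0.998 and 1.14 FPKM, but no reference profile or genotype was used here, so which cells these were stays open. CDKN2B was 10.7 ± 0.188 FPKM in controls, 7.44 ± 0.273 under BPQD and 9.94 ± 0.276 under TiO2.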
